A study of Mus musculus with 21 samples.

How the data were processed

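RNA was measured in 21 libraries from 3 bone marrow progenitor populations of mice that were wild type or homozygous for a mutation of Etv6, a transcriptional repressor of the ETS family. The series' description writes the mutation as h.P214L. Per the labels' protocols, cells were sorted by flow cytometry into lysis buffer, total RNA was purified, and polyadenylated RNA was turned into cDNA with a SMART-seq kit. Libraries were then made by tagmentation with the NexteraXT kit. The labels give separate mice, 3 wild type and 4 mutant, and each population has 3 wild-type and 4 mutant libraries. The replicate number was taken as the mouse, because the numbers match the mice counted in the description. Across populations of 1 genotype, deviations from the group means of same-numbered libraries correlated at 0.094 to 0.481 over genes, above 0.1 in 19 of 21 pairs. Libraries of different numbers were not compared, and same-numbered libraries of different genotypes, which are different mice, reached 0.453. These correlations therefore do not show that a number marks a mouse. Mutant libraries numbered 4 are labelled as 10 weeks old in 1 population and 12 weeks old in the other 2. Unless an age label is wrong, this speaks against reading number 4 as 1 mouse. The ages were left as labelled. Fits with the mouse as a block rest on that reading, as do splits of the mice for results that span populations. Each population was represented by mice of both sexes. The table holds 0 members of a list of sex-linked genes, so the labelled sex was not checked against expression.

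The values were deposited as RPKM, a unit that divides the reads of a gene by its transcript length and by the mapped reads of its library, in 1 table of 11628 genes. Per the submitters' processing notes, reads were aligned with STAR to the mouse genome mm10. The STAR version, the counting tool, the gene annotation, the strand setting and the rule that chose the 11628 genes are not given in the sources used here. Such a table holds no counts, and none were recovered from the values, so sequencing depth is unknown and no counting interval was given. In its place, RPKM summed to between 337818 and 376135 per library, the median gene lay between 12.0 and 13.6 RPKM, and the upper quartile lay between 29.6 and 30.6 RPKM. Between 10491 and 11236 genes reached 1 RPKM, the 10 most abundant genes held 3.02% to 4.30% of the sum, and 2 to 90 genes stood at 0. Libraries of one group correlated at 0.968 to 0.990 (Pearson, log2 scale, over genes), and 0 pairs of libraries were identical. The upper quartiles were closer to one another than the sums, so values may already have been scaled between libraries; whether they were is not given in the sources used here. RPKM divides by the mapped reads of a library and by transcript length. Reads taken by a few abundant genes, or a length-dependent loss of RNA, would therefore shift other values. SMART-seq amplifies full-length polyadenylated cDNA from little RNA and does not mark strand, so rare transcripts are noisy, and genes that overlap on opposite strands cannot be told apart. Near-identical genes, such as the paired globin genes, are uncertain individually because the treatment of shared reads is not stated.

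Symbols were read as deposited. A spreadsheet had turned 16 symbols into dates, and these were restored through the Entrez identifiers, 11619 of which matched the RefSeq annotation of GRCm38, the assembly also called mm10. Coordinates are from that annotation, 1-based. Genes were kept where at least 3 libraries reached 1 RPKM, which left 11496 genes and removed 132. Values were analysed as log2(RPKM + 1), a scale that understates changes of genes near or under 1 RPKM. Group means of all 6 groups were fitted in limma 3.58.1 (R 4.3.3) with a variance trend, so that all 21 libraries shared the estimate of spread, with 15 residual and 4.62 prior degrees of freedom. Contrasts were mutant minus wild type in each population, the 3 differences of those effects between populations, and the wild-type differences between populations. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The Etv6 transcript was compared by an exact two-sided permutation test over the 35 splits of 7 libraries, whose smallest p is 0.0286, with adjustment over 3 populations.

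Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives, except where the closing text says otherwise. Of 24 lists, 23 had at least 5 kept members and were tested. They covered interferon-stimulated genes, the NF-kB and TNF response, pattern recognition and cytokine receptors, immediate early and heat shock genes, early lymphoid genes, B-lineage genes, and T, NK and innate lymphoid genes. They also covered stem cell, megakaryocyte and platelet, erythroid, neutrophil granule, monocyte and macrophage, dendritic cell and MHC class II, mast cell and basophil, stromal and endothelial, and plasma cell genes. The remainder were proliferation, p53 targets, the unfolded protein response, homing and adhesion, cytoplasmic ribosomal proteins, oxidative phosphorylation and the genes of the sorting gates. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 23 lists, and again with the correlation estimated from the data and with fry. Members were also counted with adjustment over the list alone.

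Named genes were, for each genotype comparison, up to 8 called genes per direction with the largest fold changes whose mutant and wild-type values did not overlap. Predicted genes, receptor segments, histone genes and sex-linked genes were excluded from these. Etv6, the gate genes, up to 4 called members of each list, and up to 2 members with the smallest p of a list without any were added. Where a comparison called nothing, the 5 genes with the smallest p are given as values. Of each difference of genotype effects, up to 5 called genes are named, and of each wild-type comparison the gate genes and up to 3 called members of each list. Up to 10 genes called in all 3 populations would have been named. Hbb-bs, a globin gene, is named outside this rule, after its values were seen. One called gene is not reported here. The alternatives changed the pseudocount (0.1 and 0.5), the filter, the scaling between libraries, the variance model, library weights, terms for sex and age, the libraries in the fit, a block for the replicate number or mouse, a fold threshold and each library in turn. The fitting code was tested on simulated data made from these libraries' means and spread with known changes. At a true log2 change of 1, limma called 86.5% of the changed genes in the HSC comparison, 90.5% in the MPP4 comparison and 92.5% in the CLP comparison over 11496 genes. At a true log2 change of 0.5 the shares were 59.6%, 44.3% and 51.5%. The simulation changed more genes than were called in the real comparisons, which loosens the adjusted threshold. It drew independent noise for each value, without structure shared between libraries or genes. These shares check the code and are not the power behind the real counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.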

Results

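The study compared blood progenitors of wild-type mice with those of mice homozygous for a mutation in Etv6, the mouse counterpart of a gene in which inherited human mutations cause low platelet counts and a leukaemia predisposition. Its stated interest was inflammation and lymphoid development. Bone marrow was sorted into 3 populations. Haematopoietic stem cells (HSC) were taken as lineage-negative, cKit- and Sca1-positive, FLK2-negative, CD150-positive and CD38-negative. The lymphoid-biased multipotent progenitors (MPP4) were lineage-negative and positive for cKit, Sca1 and FLK2. Common lymphoid progenitors (CLP) were lineage-negative, IL7- and Flk2-positive with low cKit and Sca1. Each population had 3 wild-type and 4 mutant libraries from mice 10 or 12 weeks old. Values are RPKM, given as mean ± SD, and fold changes are on the log2(RPKM + 1) scale. Depth is unknown, and RPKM summed to between 337818 and 376135 per library. The first principal component held 71.0% of the variance over genes.

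Wild-type MPP4 carried far more transcript of lymphoid genes and far less of stem cell genes than wild-type HSC. Flt3, the FLK2 receptor of the gate, stood at 384 ± 33.4 RPKM in MPP4 against 14.9 ± 1.91 in HSC (n = 3 each), and Slamf1, which encodes CD150, at 0.849 ± 0.534 against 22.6 ± 5.26. Dntt, the polymerase that adds untemplated bases to antigen receptor genes, stood at 889 ± 149 against 4.19 ± 1.06. Tek, the angiopoietin receptor, fell from 27.5 ± 4.61 to 0.670 ± 0.229. The limma fit called 4522 genes after Benjamini-Hochberg adjustment, 1849 higher and 2673 lower in MPP4. Of 44 early lymphoid genes 33 rose and 2 fell, and of 41 stem cell genes 38 fell and 2 rose. Of 10 lists called by camera, these were the 2 that held with an estimated correlation (Benjamini-Hochberg adjusted p = 0.00385 for each). Of 48 proliferation genes 47 rose, including Aurkb, a mitotic kinase, at 92.9 ± 5.77 against 30.5 ± 10.5 RPKM. That list's camera call was lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.312), as was that of the megakaryocyte and platelet genes, of which 27 of 38 fell (0.317). Cd38, whose product the labels give as absent from the gated HSC, stood at 8.39 ± 1.89 RPKM in HSC and 1.67 ± 0.339 in MPP4, and Cd48 at 4.71 ± 1.09 and 169 ± 18.0. Whether CD38 is the marker that was stained was not checked.

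From MPP4 to CLP in wild type, B-cell genes rose and the remaining stem cell transcripts fell. Il7r, the interleukin-7 receptor, stood at 91.3 ± 3.73 RPKM in CLP against 11.6 ± 4.01 in MPP4, Ly6d, a surface marker of B-committed lymphoid progenitors, at 881 ± 213 against 21.3 ± 13.3, and Blk, a Src-family kinase of B cells, at 70.4 ± 27.6 against 4.57 ± 1.79. Hlf, a transcription factor of stem cells, fell by 2.98 on the log2 scale, from 19.9 ± 3.60 to 1.62 ± 0.230 RPKM. Kit stood at 39.9 ± 7.96 against 151 ± 19.9 and Ly6a, which encodes Sca1, at 26.4 ± 9.73 against 56.4 ± 12.7, and both passed the test. The limma fit called 1511 genes after Benjamini-Hochberg adjustment, 548 higher and 963 lower in CLP. Of 44 early lymphoid genes 25 rose and 4 fell, of 29 B-lineage genes 19 rose, of 19 T, NK and innate lymphoid genes 10 rose, and of 41 stem cell genes 21 fell. These were the 4 of 9 list calls by camera that held with an estimated correlation, with Benjamini-Hochberg adjusted p = 0.00507, 0.00613, 0.0112 and 0.0112 in that order. The level of Siglech, a receptor of plasmacytoid dendritic cells, was 87.9 ± 38.7 RPKM in CLP and 2.89 ± 1.12 in MPP4. Its list, dendritic cell and MHC class II genes, had 7 of 22 members higher, and its camera call was lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.270).

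The Etv6 transcript (chromosome 6, 134035700 to 134270158) did not differ between genotypes beyond the spread between mice. It stood at 105 ± 7.48 RPKM in mutant (n = 4) against 113 ± 6.91 in wild-type HSC (n = 3), 85.1 ± 3.49 against 89.4 ± 5.71 in MPP4 and 65.6 ± 4.68 against 70.3 ± 8.04 in CLP. The log2 differences were -0.10, -0.07 and -0.10, with exact permutation p = 0.400, 0.286 and 0.457 (0.457 for each after Benjamini-Hochberg adjustment over the 3 populations). A point mutation need not change the amount of its transcript, so these values do not check the genotype labels.

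In HSC, 5 genes were lower and 1 was higher in mutant mice. Gmfg, a regulator that prunes branched actin filaments (chromosome 7, 28437469 to 28448230), fell from 86.2 ± 19.5 RPKM in wild type to 33.9 ± 6.63 in the mutant, a log2 change of -1.32 ± 0.15 (SE). Plac8, a gene of early myeloid and lymphoid progenitors (chromosome 5, 100551589 to 100572253), fell from 68.8 ± 18.2 to 34.7 ± 1.47, Sox18, a transcription factor of endothelium (chromosome 2, 181669837 to 181671640), from 11.9 ± 3.58 to 4.39 ± 1.98, and Smim5, a small membrane protein gene, from 47.6 ± 10.9 to 21.5 ± 3.59. Fam105a also fell, from 7.98 ± 0.674 to 5.01 ± 0.512. Matn4, an extracellular matrix protein gene (chromosome 2, 164389393 to 164405160), rose from 1.27 ± 0.386 to 3.23 ± 0.727. In limma with Benjamini-Hochberg adjustment, adjusted p was 3.30e-04 for Gmfg, 0.00993 for Plac8, Smim5 and Matn4, 0.0171 for Sox18 and 0.0216 for Fam105a. Unadjusted p lay under 0.05 for 512 genes, where 575 are expected by chance. Gate genes were not called: Kit stood at 312 ± 18.6 against 332 ± 53.9 RPKM, Slamf1 at 26.7 ± 3.69 against 22.6 ± 5.26, and Cd38 at 5.34 ± 1.82 against 8.39 ± 1.89.

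Lists of genes had small median changes in mutant HSC. Cytoplasmic ribosomal protein genes had a median log2 change of -0.16, with 82 of 84 members negative and 0 called, and oxidative phosphorylation genes -0.09, with 68 of 77 negative and 0 called. Genes of the unfolded protein response, the endoplasmic reticulum's answer to misfolded protein, had a median of -0.16, with 20 of 24 negative and 0 called; its member Pdia6, a protein disulfide isomerase, stood at 95.6 ± 8.97 against 115 ± 12.6 RPKM. Neutrophil granule genes had a median of -0.41 and 1 called member, Plac8, which is also on the early lymphoid list (median -0.03, 1 of 44 fell). In the neutrophil list 1 library stood apart, HSC_WT replicate 2, with a mean of 4.92 log2 units against 2.90 and 3.22 in the other wild-type libraries. Homing and adhesion genes had a median of -0.09, dendritic cell and MHC class II genes -0.07, interferon-stimulated genes -0.05, and erythroid genes 0.18, with 0 called in each. Adjusted over the list alone, 1 early lymphoid, 1 neutrophil, 1 dendritic cell and 1 B-lineage gene were lower and 1 erythroid gene was higher. These 9 lists passed camera at the preset correlation, with Benjamini-Hochberg adjusted p from 6.75e-15 for ribosomal proteins to 0.0322 for erythroid genes. With an estimated correlation all 9 calls were lost: camera's Benjamini-Hochberg adjusted p was 0.334 for the unfolded protein response and for homing, 0.552 for neutrophil, 0.633 for early lymphoid and for dendritic cell, 0.691 for ribosomal, 0.723 for oxidative phosphorylation, and 0.863 for interferon-stimulated and for erythroid genes. The inflammation lists gave Benjamini-Hochberg adjusted p = 0.216 (NF-kB and TNF response), 0.906 (pattern recognition and cytokine receptors) and 0.794 (immediate early and heat shock) in camera. The other lists gave 0.906 (stem cell), 0.216 (megakaryocyte and platelet, and monocyte and macrophage), 0.623 (B-lineage), 0.773 (T, NK and innate lymphoid), 0.729 (mast cell), 0.680 (stromal), 0.361 (plasma cell, and proliferation), 0.469 (p53 targets) and 0.183 (gate genes). The gene count was 0 when HSC libraries alone entered the fit, 12 with quantile normalization, 21 with library weights, 3 without HSC_WT replicate 2 (Gmfg and Plac8 of the 6) and 2 without HSC_WT replicate 3 (Gmfg and Matn4). Sox18 and Fam105a were also lost without HSC_HOMO replicate 2 or 3, and Matn4 without HSC_WT replicate 1. Without HSC_WT replicate 3 the ribosomal mean change was 0.01, and without HSC_WT replicate 2 the neutrophil mean change was 0.10, in place of -0.16 and -0.53. Of the other list calls, those of oxidative phosphorylation, homing, interferon-stimulated, early lymphoid and erythroid genes were lost without HSC_WT replicate 3 (means -0.02, -0.09, 0.01, -0.05 and -0.02). Those of dendritic cell and early lymphoid genes were lost without HSC_WT replicate 2 (-0.02 and -0.04). Interferon-stimulated genes were lost without HSC_HOMO replicate 1 or 2 (-0.03 and 0.01), homing without HSC_HOMO replicate 2 (-0.06), neutrophil without HSC_HOMO replicate 4 (-0.35), and erythroid genes without HSC_WT replicate 1 or HSC_HOMO replicate 2 or 3 (0.16, 0.02 and 0.16). Calls that stood also moved in size. The erythroid mean of 0.26 was 0.65 without HSC_WT replicate 2, 0.41 without HSC_HOMO replicate 1 and 0.46 without HSC_HOMO replicate 4, and the neutrophil mean was -0.91 without HSC_WT replicate 3. Without HSC_WT replicate 1 the means of ribosomal, oxidative phosphorylation, early lymphoid and dendritic cell genes were -0.27, -0.12, -0.16 and -0.19, in place of -0.16, -0.08, -0.08 and -0.12. Oxidative phosphorylation was at -0.03 and -0.12 without HSC_HOMO replicates 1 and 4, dendritic cell genes at -0.07 without HSC_HOMO replicate 1, and interferon-stimulated genes at -0.14, -0.13 and -0.14 without HSC_WT replicate 2 and HSC_HOMO replicates 3 and 4, in place of -0.07.

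In MPP4, 12 genes were higher and 13 lower in mutant mice. Among the higher, Hlf, a transcription factor of stem cells (chromosome 11, 90336535 to 90390917), rose from 19.9 ± 3.60 RPKM in wild type to 39.8 ± 3.81 in the mutant. Gng11, a G-protein gamma subunit of platelets (chromosome 6, 4003987 to 4008445), rose from 2.89 ± 0.679 to 10.5 ± 3.76, and Gas6, the ligand of the TAM receptor kinases (chromosome 8, 13465374 to 13494535), from 9.06 ± 0.557 to 18.7 ± 2.41. Cox6a2, a cytochrome c oxidase subunit found in plasmacytoid dendritic cells (chromosome 7, 128205435 to 128206366), fell from 33.8 ± 9.08 to 10.2 ± 4.02, and Irf8, a transcription factor of dendritic cells and monocytes (chromosome 8, 120736358 to 120756694), from 48.8 ± 2.46 to 28.2 ± 4.89. Cnn3, an actin-binding calponin of early lymphoid cells (chromosome 3, 121426541 to 121458205), fell from 90.7 ± 13.3 to 38.2 ± 6.90. Blnk, the adaptor of the pre-B-cell receptor (chromosome 19, 40928927 to 40994221), fell from 22.4 ± 9.16 to 9.95 ± 1.44, and Blk (chromosome 14, 63372837 to 63417187) from 4.57 ± 1.79 to 1.38 ± 0.377.

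Altogether 25 genes were called in MPP4, 12 higher and 13 lower, with unadjusted p under 0.05 for 936 genes against 575 expected by chance. In limma with Benjamini-Hochberg adjustment, adjusted p was 0.00203 for Gng11, 0.00669 for Gas6, 0.0364 for Hlf and Irf8, 0.00150 for Cox6a2 and Cnn3, 0.0413 for Blnk and 0.0466 for Blk. Log2 changes ran from 1.53 ± 0.21 (SE) for Gng11 to -1.67 ± 0.22 for Cox6a2. Also higher were Scarf1, a scavenger receptor (7.52 ± 2.05 against 3.27 ± 0.587 RPKM), Tob1, an antiproliferative factor (a log2 change of 0.87), Prkcdbp, a caveola protein gene (6.51 ± 0.950 against 3.13 ± 0.486), and Slc27a6, a fatty acid transporter gene (3.05 ± 0.743 against 1.34 ± 0.315). Also lower were Cd6, a T-cell surface receptor (3.88 ± 0.437 against 9.72 ± 2.61), Cmah, an enzyme of sialic acid synthesis (4.47 ± 0.952 against 10.5 ± 2.76), Drc7 (9.95 ± 0.779 against 21.4 ± 6.04), Camkv (1.42 ± 0.408 against 3.80 ± 1.25) and Arpp21 (2.55 ± 0.836 against 5.18 ± 0.942). Further called genes were Tmem120a, Fam110c, Nfic and Rusc2, which were higher, and Myo7a, Rasal1 and Unc93b1, which were lower. Gate genes were not called: Flt3 stood at 383 ± 17.5 against 384 ± 33.4 RPKM (limma, Benjamini-Hochberg adjusted p = 0.999), Kit at 176 ± 13.2 against 151 ± 19.9 and Il7r at 7.09 ± 1.34 against 11.6 ± 4.01 (adjusted p = 0.445). Scaling moved the split of higher to lower calls from 12 and 13 to 8 and 14 (median-ratio) or 5 and 15 (quantile), and the count was 0 with a pseudocount of 0.1, 14 with 0.5, 184 with library weights, 42 with a sex term, 48 with sex and age terms, and 3 (Gas6, Hlf and Cnn3) with MPP4 libraries alone. It was 7 without MPP4_WT replicate 3, 14 without MPP4_WT replicate 2, 11, 16, 14 and 15 without MPP4_HOMO replicates 1, 2, 3 and 4, and 8 without both replicate 1 libraries, an alternative added after the data were seen. Cd6, Cmah, Cox6a2, Gng11 and Cnn3 were called without any one MPP4 library, and each other gene named here was lost without at least 1.

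**Figure D1:**
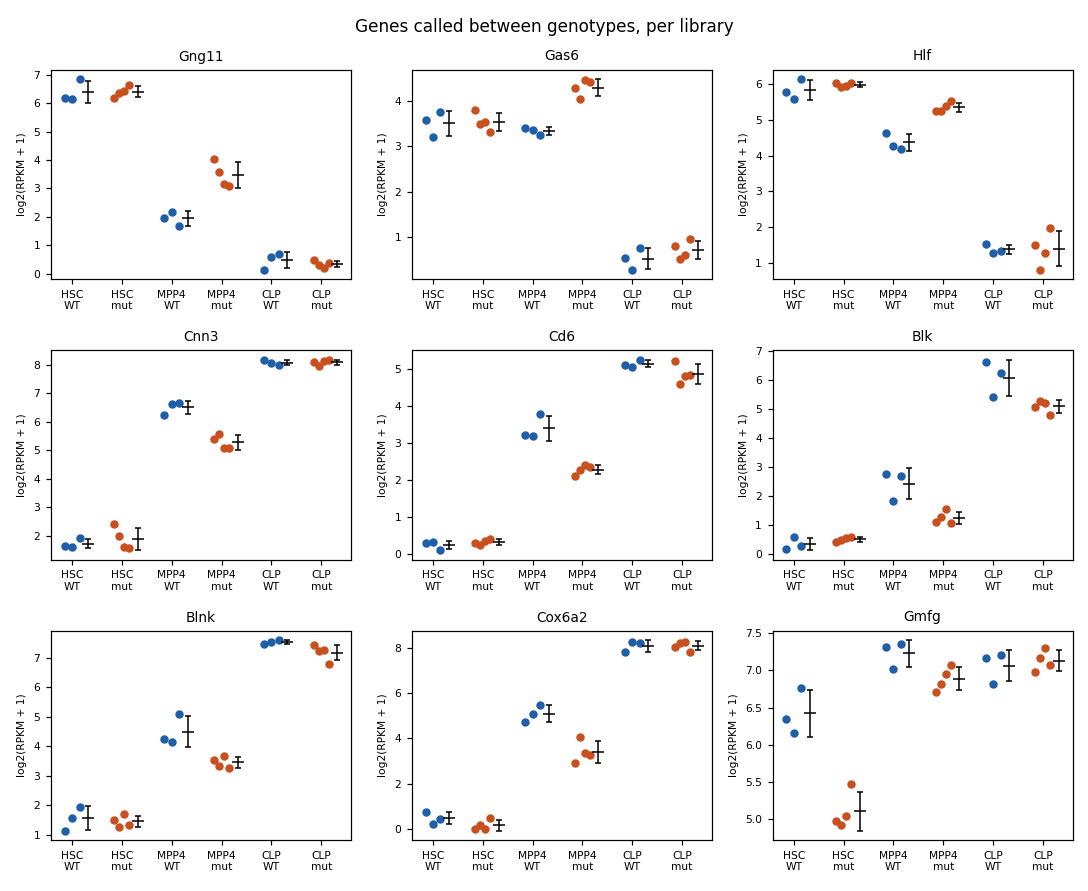
Expression of 9 genes in each library, as log2(RPKM + 1), by population and genotype; points are libraries (blue wild type, n = 3; orange mutant, n = 4) and black bars are the mean ± SD. In MPP4 the mutant points lie above the wild-type points for Gng11, Gas6 and Hlf and below them for Cnn3, Cd6, Blk, Blnk and Cox6a2, and in HSC they lie below them for Gmfg.

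Stem cell genes had a median log2 change of 0.35 in mutant MPP4, with 38 of 41 positive. Of these, 2 members, Hlf among them, passed over all genes and 10, all higher, adjusted over the list alone, and the camera call was lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.179). Megakaryocyte and platelet genes had a median of 0.39 with 34 of 38 positive; 2 members, Gng11 among them, passed over all genes and 5, all higher, adjusted over the list alone. That call was lost likewise (camera, Benjamini-Hochberg adjusted p = 0.424 with an estimated correlation). Erythroid genes had the largest median, 1.10, with 32 of 32 positive; 0 passed over all genes and 16, all higher, adjusted over the list alone. The call was lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.255). The members with the smallest p were Epor, the erythropoietin receptor (2.81 ± 0.656 against 0.831 ± 0.648 RPKM), and Aqp1, a water channel of red cells (11.3 ± 4.15 against 3.20 ± 2.44). Early lymphoid genes had a median of -0.10; 3 of 44 fell (Cnn3, Blnk and Arpp21), and 9 were lower adjusted over the list alone. With an estimated correlation camera gave a Benjamini-Hochberg adjusted p = 0.179. Dendritic cell and MHC class II genes had a median of -0.01 and 2 of 22 fell, Cox6a2 and Irf8, with 3 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.424 with an estimated correlation). Ribosomal protein genes had a median of -0.17, with 84 of 84 negative, oxidative phosphorylation genes -0.11, proliferation genes -0.13 with 43 of 48 negative, unfolded protein response genes -0.17, plasma cell genes -0.17 and mast cell and basophil genes 0.23, with 0 called in each. Adjusted over the list alone, 4 unfolded protein response genes were lower and 1 was higher, 1 plasma cell gene was lower, and 0 passed in the other 4 lists. With an estimated correlation these calls were lost too, at camera Benjamini-Hochberg adjusted p = 0.479, 0.424, 0.742, 0.304, 0.396 and 0.424 in that order. Of B-lineage genes 2 of 29 fell, Blnk and Blk, and the median was 0.03; camera did not call the list (Benjamini-Hochberg adjusted p = 0.203). Among lists not called, those adjusted over the list alone were 2 lower B-lineage and 2 lower monocyte genes, 1 higher and 2 lower genes in each of the neutrophil and homing lists, and 1 higher and 1 lower in each of the T, NK and innate lymphoid and p53 lists.

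These 11 lists passed camera at the preset correlation, with Benjamini-Hochberg adjusted p = 2.52e-15 for erythroid and for ribosomal genes, 1.06e-09 for stem cell, 4.70e-10 for oxidative phosphorylation, 9.56e-07 for megakaryocyte, 1.09e-06 for early lymphoid, 2.24e-05 for proliferation, 5.95e-05 for unfolded protein, 0.00822 for dendritic, 0.0281 for mast and 0.0373 for plasma cell genes. With an estimated correlation camera called 0 lists, at the adjusted p given beside each list. The fry test, which asks whether the members of a list move one way on balance, called 1 list, stem cell genes (Benjamini-Hochberg adjusted p = 0.0394). Its version for members that move either way called 10 lists in MPP4, 0 in HSC and 0 in CLP. That version does not compare a list with the other genes. The inflammation lists were not called by camera: Benjamini-Hochberg adjusted p was 0.124 for interferon-stimulated genes, 0.129 for the NF-kB and TNF response, 0.387 for pattern recognition and cytokine receptors and 0.636 for immediate early and heat shock genes. The remaining lists gave 0.813 (T, NK and innate lymphoid, and stromal), 0.744 (neutrophil, and monocyte and macrophage), 0.848 (p53 targets, and homing) and 0.616 (gate genes). Psmb8, an interferon-inducible proteasome subunit, had a log2 change of -0.42 ± 0.11 (SE), and Csf1r, the macrophage growth factor receptor, at 14.9 ± 1.73 against 31.9 ± 8.01, neither called (limma, Benjamini-Hochberg adjusted p = 0.153 and 0.0740). The library MPP4_HOMO replicate 1 had a mean of 4.45 log2 units over megakaryocyte genes against 2.56 to 2.72 in the other mutant libraries, and MPP4_WT replicate 1 had 3.15 against 2.35 and 2.36 in the other wild-type libraries. Slamf1 was also highest in MPP4_HOMO replicate 1, at 3.20 RPKM against 1.13 to 1.34. Globin transcripts varied between MPP4 libraries, with Hbb-bs at 124 RPKM in MPP4_WT replicate 2 and 727 to 2529 in the other 6. The megakaryocyte call was lost without MPP4_HOMO replicate 1 alone, where its mean change was 0.01 in place of 0.47. Without both replicate 1 libraries its mean change was 0.28, and the call at the preset correlation stood. The count of erythroid genes over the list alone was 0 without MPP4_WT replicate 3, 0 without MPP4_HOMO replicate 2, 4 without MPP4_HOMO replicate 4 and 0 with a pseudocount of 0.1; stem cell genes numbered 5 without MPP4_WT replicate 3 and 6 without MPP4_HOMO replicate 1 or 4, and early lymphoid genes 4 without MPP4_WT replicate 3. Megakaryocyte and platelet genes over the list alone numbered 2 without MPP4_WT replicate 2 and 2 without MPP4_WT replicate 3. The 5 unfolded protein response genes became 0 without MPP4_WT replicate 1 or 2 or MPP4_HOMO replicate 4, 1 without MPP4_WT replicate 3, 2 without MPP4_HOMO replicate 1 or 3, and 8 without MPP4_HOMO replicate 2. The dendritic cell call was lost without MPP4_HOMO replicate 2 (mean -0.03), the mast cell call without MPP4_WT replicate 3, MPP4_HOMO replicate 2 or 3 (0.37, 0.41 and 0.24), and the plasma cell call without MPP4_WT replicate 3, MPP4_HOMO replicate 1 or 2 (-0.12, -0.13 and -0.18). Calls that stood also moved in size. The proliferation mean of -0.13 was -0.07 without MPP4_WT replicate 2 and -0.21, -0.21, -0.05 and -0.06 without MPP4_HOMO replicates 1 to 4. Oxidative phosphorylation went from -0.10 to -0.05 and ribosomal genes from -0.17 to -0.10 without MPP4_HOMO replicate 1, and ribosomal genes to -0.11 and early lymphoid genes from -0.18 to -0.11 without MPP4_WT replicate 3. Megakaryocyte genes were at 0.73 without MPP4_WT replicate 1, and dendritic cell genes at -0.03, -0.16 and -0.15 without MPP4_HOMO replicates 1, 3 and 4, in place of -0.09.

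In CLP, 0 genes were called. Blk stood at 33.3 ± 5.07 RPKM in mutant against 70.4 ± 27.6 in wild type and Tnfrsf13c, the receptor for the B-cell survival factor BAFF, at 7.28 ± 0.923 against 12.1 ± 1.73. Over 29 B-lineage genes the median log2 change was -0.30, with 25 negative, 0 called over all genes and 2 lower adjusted over the list alone. The library CLP_HOMO replicate 4 had the lowest B-lineage mean, 3.53 log2 units, against 3.74 to 4.38 in the other mutant libraries and at least 4.02 in the wild-type libraries. On the second principal component of all 21 libraries it lay at 1.32, against 12.997 to 17.6 for the other CLP libraries. Without it the mean B-lineage change was -0.26 in place of -0.37, and 0 genes were called. The genes with the smallest p were Mfge8, a secreted bridge between apoptotic cells and phagocytes (a log2 difference of 0.39 ± 0.07, SE, from 26.5 ± 0.951 RPKM in wild type), Slc25a30, a mitochondrial carrier gene (1.98 ± 0.499 against 3.89 ± 0.517), Pik3r6, a phosphoinositide 3-kinase regulatory subunit (3.16 ± 1.45 against 7.45 ± 1.67), Il18r1, the interleukin-18 receptor (7.83 ± 0.871 against 3.90 ± 1.51), and 9330175E14Rik, which overlaps Nlrc5 (3.57 ± 0.951 against 6.54 ± 1.35). Their limma Benjamini-Hochberg adjusted p was 0.313, and 0.356 for 9330175E14Rik; unadjusted p lay under 0.05 for 507 genes against 575 expected by chance. The gate genes Il7r (89.8 ± 10.7 against 91.3 ± 3.73 RPKM), Flt3 (381 ± 20.6 against 366 ± 23.8) and Kit (39.3 ± 5.98 against 39.9 ± 7.96) were not called. Without CLP_HOMO replicate 2 the count was 5, among them Mfge8 and Pik3r6, with log2 changes of 0.44 and -1.28.

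At the preset correlation, camera called 8 lists in CLP, and of lists not called, 1 pattern recognition and 1 T, NK and innate lymphoid gene were higher and 1 plasma cell gene was lower adjusted over the list alone. B-lineage genes (Benjamini-Hochberg adjusted p = 2.61e-08), interferon-stimulated genes (2.55e-05), unfolded protein response genes (2.51e-04) and early lymphoid genes (0.0352) were lower, with medians of -0.30, -0.13, -0.17 and -0.04. Ribosomal protein (2.23e-07), oxidative phosphorylation (8.87e-06), monocyte and macrophage (0.00202) and proliferation genes (0.00263) were higher, with medians of 0.13, 0.09, 0.30 and 0.17, and 0 members were called in any of the 8. With an estimated correlation all 8 calls were lost: camera's Benjamini-Hochberg adjusted p was 0.236 for B-lineage, 0.745 for unfolded protein, 0.912 for proliferation and 0.881 for each of the other 5 lists. Examples were Nlrc5, the activator of MHC class I genes, at 17.8 ± 1.52 against 23.0 ± 2.51 RPKM, and Tap1, its antigen peptide transporter target, at 59.3 ± 3.66 against 74.6 ± 9.56. Lyz2, the lysozyme of myeloid cells, stood at 96.4, 369, 189 and 392 RPKM in mutant replicates 1 to 4 against 124 to 138 in wild type. In CLP_HOMO replicates 2 and 4 the neutrophil mean was 5.64 and 5.81 log2 units, against 3.27 and 4.20 in the other mutant and 4.21 to 4.72 in the wild-type libraries. The monocyte mean was 4.97 in CLP_HOMO replicate 4, against 3.76 to 4.35 in the other mutant and 3.50 to 4.47 in the wild-type libraries. The other lists gave camera Benjamini-Hochberg adjusted p = 0.635 (NF-kB and TNF response, immediate early and heat shock, and T, NK and innate lymphoid), 0.0603 (stem cell, and plasma cell), 0.0604 (erythroid), 0.623 (p53 targets), 0.850 (neutrophil) and 0.779 (pattern recognition, megakaryocyte, dendritic, mast, stromal, homing, and gate genes). The library CLP_HOMO replicate 1 had the lowest erythroid mean, 1.56 log2 units, against 3.26 to 3.93 in the other mutant libraries. Among lists not called, the median, mean and test direction differed in sign in 5 lists of HSC, 7 of MPP4 and 1 of CLP; in called lists they did not differ. The ribosomal and oxidative phosphorylation calls were lost without CLP_WT replicate 2, where the mean changes were 0.01 and -0.01, and the monocyte call was lost without CLP_WT replicate 1 (mean 0.10) or CLP_HOMO replicate 4 (0.09) in place of 0.33. The ribosomal call was also lost without CLP_HOMO replicate 3 (0.04), the proliferation call without CLP_WT replicate 2 or 3 or CLP_HOMO replicate 1 (0.09, 0.09 and 0.11), and the early lymphoid call without CLP_WT replicate 2 or 3 or CLP_HOMO replicate 3 or 4 (-0.02, -0.08, -0.08 and -0.03). The interferon call was lost without CLP_WT replicate 3 (mean -0.06 in place of -0.15), and the 2 B-lineage genes called over the list alone became 8 without CLP_HOMO replicate 2, 0 without CLP_WT replicate 1 or CLP_HOMO replicate 4, and 1 without CLP_WT replicate 2 or CLP_HOMO replicate 1 or 3. Calls that stood also moved in size. The B-lineage mean was -0.24 without CLP_WT replicate 2, and the interferon mean -0.26 without CLP_WT replicate 2 and -0.10 without CLP_HOMO replicate 2. Without CLP_WT replicate 1 the means of early lymphoid, oxidative phosphorylation and proliferation genes were -0.16, 0.15 and 0.25, in place of -0.09, 0.09 and 0.15, and early lymphoid genes were at -0.15 without CLP_HOMO replicate 2. The monocyte mean was 0.59 and the ribosomal mean 0.20 without CLP_WT replicate 3, 0.50 and 0.20 without CLP_HOMO replicate 1, in place of 0.33 and 0.13, and oxidative phosphorylation was at 0.06 without CLP_HOMO replicate 3.

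**Figure D2:**
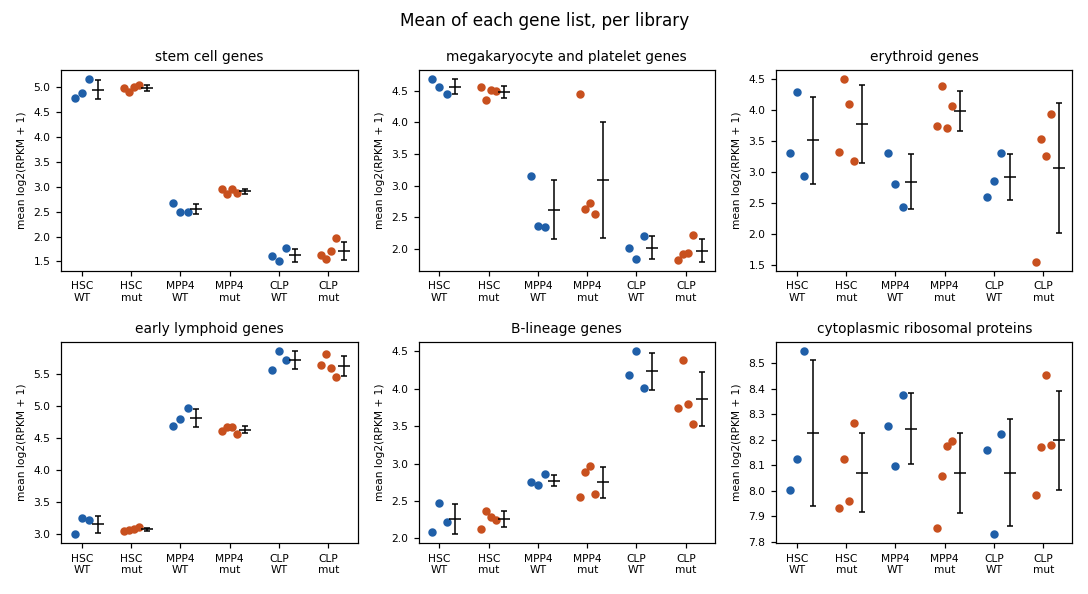
Mean log2(RPKM + 1) over the members of 6 gene lists in each library, by population and genotype; points are libraries (blue wild type, n = 3; orange mutant, n = 4) and black bars are the mean ± SD. In MPP4 the 4 mutant libraries lie at 2.86 to 2.96 for stem cell genes against 2.49 to 2.67 in wild type, and MPP4_HOMO replicate 1 stands apart at 4.45 for megakaryocyte and platelet genes.

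The genotype effect on Gmfg differed between populations. It was -1.32 log2 units in HSC, -0.34 in MPP4 and 0.07 in CLP, and the difference between CLP and HSC was 1.38 ± 0.21 (SE; limma, Benjamini-Hochberg adjusted p = 0.0273). This was the 1 gene called among the differences of genotype effect between populations, and unadjusted p lay under 0.05 for 420 genes (CLP minus HSC), 436 (MPP4 minus HSC) and 442 (CLP minus MPP4), with 575 expected by chance. With the mouse as a block, limma also called the CLP minus HSC difference of Plac8 (1.03 ± 0.14, Benjamini-Hochberg adjusted p = 0.0111) and the MPP4 minus HSC differences of Gmfg (0.98 ± 0.14) and Cnn3 (-1.40 ± 0.21), both at 0.0408, and Gmfg kept its CLP minus HSC call (5.97e-04). Plac8 and Cnn3 are named here after their values were seen. No gene was called in more than 1 population. HSC and MPP4 shared 0 calls of the same direction, where 0.0067 are expected from independent lists, and 0 genes were called in all 3. For the gene lists, camera at the preset correlation called a larger effect in MPP4 than in HSC for stem cell (median difference 0.30), megakaryocyte (0.44) and erythroid genes (0.83) and the NF-kB and TNF response (0.15), and a lower one for proliferation (-0.20). Benjamini-Hochberg adjusted p was 5.58e-07, 2.21e-07, 1.29e-06, 0.0331 and 1.56e-05 in that order. All 5 were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.474, 0.759, 0.759, 0.759 and 0.862). For CLP minus HSC camera called 7 lists at the preset correlation, lower for B-lineage and higher for neutrophil, monocyte, dendritic, homing, ribosomal and oxidative phosphorylation genes. All 7 were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.657 for each). For CLP minus MPP4 it called 10, lower for B-lineage, stem cell, megakaryocyte and erythroid and higher for early lymphoid, monocyte, dendritic, proliferation, ribosomal and oxidative phosphorylation genes. All 10 were lost likewise (camera, Benjamini-Hochberg adjusted p = 0.666 for monocyte, 0.593 for proliferation and 0.533 for each other list). The Gmfg call was lost without a variance trend, with library weights, and without any of 8 single libraries: HSC_WT replicate 3, HSC_HOMO replicates 1, 2 and 3, CLP_WT replicates 1 and 2, and CLP_HOMO replicates 3 and 4. Limma's Benjamini-Hochberg adjusted p over all alternatives ran from 5.97e-04 to 0.165.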

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

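The tests of explanations and the counts over other splits of the samples in this part were chosen after the results were seen. Of 120 groups of 4 mutant values, 4 had a library far from the other 3, where chance gives about 1 in 20. MPP4_HOMO replicate 1 had a mean of 4.45 log2 units over megakaryocyte and platelet genes, against 2.56 to 2.72 in the other mutant MPP4 libraries. The same library held 3.20 RPKM of Slamf1, the CD150 gene, against 1.13 to 1.34. MPP4_HOMO replicate 2 had a mean of 4.16 log2 units over interferon-stimulated genes, against 4.38 to 4.40. Replicate 2, the male number, was also lowest for this list in each other group, at 4.48 in HSC_WT, 4.29 in HSC_HOMO, 4.08 in MPP4_WT, 3.93 in CLP_WT and 3.86 in CLP_HOMO. HSC_HOMO replicate 2 had a mean of 4.27 log2 units over immediate early and heat shock genes, against 4.14 to 4.16. The genotype effect on Gmfg differed between CLP and HSC by 1.38 log2 units.

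For the MPP4 comparison, 1 of 35 splits of the 7 libraries, the real one, gave 25 or more genes, and the highest other split gave 2. That share is the smallest that 35 splits can give. It was not adjusted over the other counts tested this way, so it does not exclude chance. For HSC, 3 of 35 splits gave as many as the 6 genes, so chance cannot be excluded; the highest other split gave 37, which points to a structure of the samples. That split set HSC replicates 1 and 2 of both genotypes, with both male libraries, apart from replicates 3 and 4, with both libraries labelled as 10 weeks old, and limma called 7 genes with sex and age terms. For CLP, 35 of 35 splits gave at least the 0 genes of the real one, and the highest gave 190, which again points to such a structure. That split set CLP_HOMO replicates 3 and 4 and CLP_WT replicates 1 and 3 apart. It kept the 3 CLP libraries labelled as 10 weeks old on that side and both male CLP libraries on the other. For the real genotypes limma still called 0 genes with sex and age terms. For CLP minus HSC, 2 of 35 splits reached the real 1 (highest other 1), so chance could not be excluded. The same holds for the camera lists: 7 of 35 splits reached the real 9 in HSC (highest other 11), 3 of 35 the real 11 in MPP4 (14) and 16 of 35 the real 8 in CLP (12). Where the real count is 0, all 35 splits reach it whatever the data, so the share tests nothing. This holds for the CLP genes and for MPP4 minus HSC (highest other 0). It also holds for CLP minus MPP4 (1) and for genes called in all 3 populations (0). For the wild-type populations, 1 of 10 splits, the real one, gave 4522 genes (MPP4 minus HSC) and 1511 (CLP minus MPP4), with 0 in the highest other; 10 splits are too few for a share under 0.05.

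Of the 25 genes called in mutant MPP4, 12 were higher and 13 lower, and stem cells carried into the mutant MPP4 sort do not account for the lower genes: 42 genes restricted to wild-type HSC implied a median share of 2.64% (quartiles 1.45% and 4.25%), while the 13 lower genes needed at least 44.3%. Nor do they account for 5 of the higher genes, Hlf, Nfic, Tmem120a, Tob1 and Gas6, which implied shares of 54.1% (Hlf) to 684% (Gas6), and at least 47.7% without any 1 of 10 libraries, while no HSC-restricted gene passed 13.9%, or 19.2% without 1 library. The other 7 higher genes implied a median of 7.33%, from 3.88% (Fam110c) to 19.3% (Rusc2, at least 18.2% without any 1 library). Of these, 3 (Fam110c, Scarf1 and Gng11) are among the 42. For the 7 together a share of stem cells, which the FLK2 gate would remove, cannot be told apart from a change within MPP4. All these shares were computed from wild-type HSC means. They do not cover mutant stem cells with another profile, other early progenitors or a changed mix of cells within the gate, which were not tested. For the 25 called genes, the median absolute log2 change was 0.961 (median SE 0.157). With sex and age terms it was 0.947 (0.155), with 25 of 25 in the same direction. By the labels, sex and age were spread similarly over both genotypes in MPP4. Those terms could therefore move the changes little, whatever the effect of sex or age. Without both libraries with megakaryocyte transcripts the median was 0.935 (0.187), with 25 of 25 in the same direction and 8 passing the test. The genes were chosen with the remaining libraries in the fit, so kept directions were likely beforehand. These values show only that the changes did not rest on those libraries alone. For the megakaryocyte and platelet list those libraries stay open, since its mean log2 change of 0.47 became 0.28 without both and 0.01 without MPP4_HOMO replicate 1 alone, and for all of these genes a difference between mice other than genotype stays open.

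Erythroid genes had a median log2 change of 1.10 in mutant MPP4, with 32 of 32 positive, 28 of the 32 at 1 RPKM or more in wild-type MPP4 and 2 also on other lists. RNA of mature red cells, which the lineage-negative gate would remove, is a candidate explanation, since Hbb-bs reached 2529 RPKM in MPP4_HOMO replicate 2. The mean of 29 non-globin erythroid genes differed by 1.09 log2 units between genotypes (exact permutation p = 0.0286, the smallest 35 splits can give) and that of 3 globin genes by 1.53 (exact permutation p = 0.114). After regression on the globin mean, a non-globin difference of 0.636 log2 units was left (exact permutation p = 0.143). The regression held no genotype term, so it also took out genotype differences that globin and non-globin genes share. Red-cell RNA and erythroid transcription in mutant MPP4 therefore cannot be told apart with these 7 libraries.

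Ribosomal protein and oxidative phosphorylation genes had medians of the same sign in each population, negative in HSC and MPP4 and positive in CLP. Spread between libraries could account for these shifts: among 6 tests of list means the smallest adjusted exact permutation p was 0.457. HSC_WT replicate 3 had a ribosomal mean of 8.55 log2 units against at most 8.12 in the other wild-type HSC libraries. Transcript length stays open: relative to the trend of all other genes over length and expression, the ribosomal median kept a share of 0.257 in HSC, 0.842 in MPP4 and 0.621 in CLP. This length test was changed after its first result was seen, by leaving the ribosomal genes out of the trend. Nothing here separates an effect of genotype from either explanation.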

How the results depend on the processing

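The alternative that left out both MPP4 libraries with megakaryocyte transcripts was chosen after the data were seen, and the others before. The 6 genes of the HSC comparison became 12 with quantile normalization, 21 with library weights, 3 with an absolute log2 fold change of at least 1, 0 with HSC libraries alone, and 2 to 7 without single libraries. The 25 genes of MPP4 became 0 and 14 with pseudocounts of 0.1 and 0.5, 184 with library weights, 42 with a sex term, 48 with sex and age terms, 9 with a log2 fold of at least 1, 3 with MPP4 libraries alone, 8 without both libraries with megakaryocyte transcripts, and 7 to 19 without single libraries. CLP stayed at 0 under every alternative except leaving out single libraries, which gave 0 to 5. The 9, 11 and 8 lists called by camera became 0, 0 and 0 with an estimated correlation and 0, 1 and 0 with fry for 1 direction. Without single libraries they became 5 to 11, 8 to 13 and 4 to 10. The 0 genes of MPP4 minus HSC became 4 with library weights and 0 to 1 without single libraries. The 1 gene of CLP minus HSC became 0 without a variance trend, 0 with library weights and 0 to 3 without single libraries, and the 0 of CLP minus MPP4 became 0 to 2. The wild-type differences gave 1402 and 461 genes at a log2 fold of at least 1, with 3742 to 4302 and 1039 to 1307 without single libraries. No gene was called in all 3 populations under any alternative. List means turned in sign, with the call lost, for interferon-stimulated genes in HSC (0.019 with library weights, 0.01 without HSC_WT replicate 3 and 0.01 without HSC_HOMO replicate 2) and erythroid genes in HSC (-0.19 with library weights and -0.02 without HSC_WT replicate 3). They also turned for neutrophil granule genes in HSC (0.10 without HSC_WT replicate 2), cytoplasmic ribosomal proteins in HSC (0.01 without HSC_WT replicate 3), dendritic cell and MHC class II genes in MPP4 (3.11e-04 without both libraries with megakaryocyte transcripts) and oxidative phosphorylation in CLP, at -0.0050 without CLP_WT replicate 2 and up to 0.15 without CLP_WT replicate 1. The cause of these moves was not tested. Apart from both turns with library weights and that of oxidative phosphorylation, 1050 values for single genes and lists stayed on their side of the threshold, 353 lost the call, 2 gained it and 41 moved. The Etv6 log2 difference ran from -0.12 to -0.05 in HSC, -0.11 to -0.02 in MPP4 and -0.15 to -0.01 in CLP without single libraries. Depth is unknown, so its limit on low genes is too.

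Replicate numbers 1 to 3 are shared by the genotypes and carry labelled sex and age: number 2 is male and number 3 is 10 weeks old. The numbers were not taken as pairs, because the labels do not say that a number marks a litter, batch or day shared across genotypes. Deviations of same-numbered libraries of the 2 genotypes correlated at -0.15 to 0.45, above 0.1 in 5 of 9 pairs. Number 2 correlated at 0.433 in HSC, 0.214 in MPP4 and 0.453 in CLP and matched best in all 3 populations, and 4 of 9 wild-type libraries in all matched their own number best. With the replicate block within a population, limma called 0 genes in HSC, 1 in MPP4 and 0 in CLP. With the replicate block by mouse, MPP4 minus HSC and CLP minus HSC each gave 2 genes and CLP minus MPP4 gave 0, and the wild-type differences gave 5120 and 1994.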

Other observations

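The test of position in this part was chosen after the results were seen. Among genes that were lower in mutant MPP4, some had close means in both genotypes in CLP, where limma called 0 genes, and others had lower means in the mutant. Cox6a2 was at 273 ± 36.8 RPKM in mutant CLP (n = 4) against 273 ± 45.0 in wild type (n = 3), Cnn3 at 272 ± 15.9 against 271 ± 17.0, Irf8 at 178 ± 14.3 against 178 ± 38.7 and Cmah, the sialic acid enzyme, at 39.0 ± 4.87 against 42.7 ± 2.31. Blk stood at 33.3 ± 5.07 RPKM in mutant CLP against 70.4 ± 27.6, Blnk at 145 ± 25.3 against 182 ± 9.01, Drc7 at 72.8 ± 9.92 against 93.2 ± 12.3 and Camkv at 21.2 ± 3.45 against 27.6 ± 1.20. In wild type, Cox6a2 rose by a log2 change of 3.00 from MPP4 to CLP and Irf8 by 1.82. The difference of genotype effect between CLP and MPP4 was not called for any gene by limma (0 genes after Benjamini-Hochberg adjustment, 442 at unadjusted p under 0.05), so these levels do not show that the effects differ. Among genes that were higher in mutant MPP4, Hlf stood at 62.0 ± 2.85 RPKM in mutant HSC against 56.7 ± 11.4 in wild type. Gas6 stood at 10.6 ± 1.61 RPKM in mutant HSC against 18.7 ± 2.41 in mutant MPP4.

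On a line from the mean of wild-type HSC (0) to the mean of wild-type CLP (1), mutant MPP4 libraries lay at 0.581 ± 0.0136 (n = 4) and wild-type MPP4 libraries at 0.686 ± 0.0287 (n = 3). The exact two-sided permutation p was 0.0286, the smallest that 35 splits allow, and 0.0857 after Benjamini-Hochberg adjustment over 3 populations. The other 2 tests placed HSC libraries on the line from wild-type MPP4 to CLP (exact permutation p = 0.886) and CLP libraries on the line from wild-type HSC to MPP4 (exact permutation p = 1.00). With those p, a shift in MPP4 alone could not have passed this adjustment, whatever its size. All 4 mutant libraries lay nearer to HSC than all 3 wild-type libraries. A less advanced average state of mutant MPP4 may underlie this, as a hypothesis that these 7 libraries leave open.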
